A study of Mus musculus with 6 samples.

How the data were processed

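The series measured brain total RNA of male mice aged 9 weeks on 6 two-colour BMAP cDNA microarrays. On each array, RNA taken 10 min after naloxone, an opioid receptor antagonist, was labelled directly with Cy5 and RNA taken 10 min after saline with Cy3. NY1DD mice, a transgenic model of sickle cell disease, filled 3 arrays, and wild-type C57BL/6J mice filled the other 3. No array had the dyes swapped, so a dye bias common to all arrays cannot be separated from naloxone in a strain mean or in the average of the strains, while it cancels in the difference between strains. The labels do not state whether the arrays, or their saline RNA, come from separate animals, so the p-values below measure the spread between arrays. The sample titles carry a number whose meaning is not stated: C57BL/6J replicates 1 and 2 share it, the other arrays each have their own, and no number occurs in both strains. If it marks a batch or a pool of RNA, the difference between strains cannot be told apart from it, and the C57BL/6J spread may come from fewer than 3 independent samples. The Pearson correlation of C57BL/6J replicates 1 and 2 was 0.148, against 0.124 and 0.127 for the other pairs of C57BL/6J arrays.

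The deposited values are natural log (ln) ratios of the 2 channels of an array. On each array their median lay close to 0 as deposited, and what brought it there is not stated. The base was read from the values: the lowest value on all 6 arrays was the natural log of 0.01, and 403 of 67941 values that are neither 0 nor at this limit were whole multiples of 0.1 after back-transformation with base e, against 1 with base 2 and 2 with base 10, at a tolerance of 1e-06. The numerator is not stated; the ratio is likely naloxone over saline, because the series' design text names Cy5 as the naloxone channel and Cy3 as the saline control. If it is the reverse, every sign turns. The normalisation, the background correction, the spot filter and the software are not given in the sources used here. Single-channel intensities were not used here, so signal over background is unknown for every value.

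The table held 11532 spots, of which 30 control spots were left out. Of the 11502 probes, 7906 had 1 gene symbol in the platform annotation, 297 had several and 3299 had none; 7894 were found by gene number in a RefSeq gene table (GRCm38.p6), and 0 of their symbols differed from it. Values were converted to log2. Values at the lower limit (293 values of 263 probes, never on all 3 arrays of a strain) were treated as missing, a choice made after the values were seen. A probe needed a value on at least 2 arrays of each strain, each array was centred on its median, and probes with the same single symbol were averaged. This left 11340 probes in 9685 features: 6146 genes and 3539 single probes with no symbol or several. Of the genes, 1311 had more than 1 probe, and 9175 features had values on all 6 arrays.

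Limma (version 3.58.1, R 4.3.3) fitted a mean per strain to all 6 arrays, with 4 residual degrees of freedom and an empirical Bayes prior of 3.13 degrees of freedom and SD 0.316. The 4 comparisons were the NY1DD mean against 0, the C57BL/6J mean against 0, NY1DD minus C57BL/6J, and the average of both strains against 0, each with Benjamini-Hochberg adjustment over 9685 features and a threshold of 0.05. All tests were two-sided. All standard errors (SE) given with a mean log2 ratio come from this model, and SD is the spread between arrays. A size rule counted features past 1.5-fold on the same side on every array of a strain, set beside the count after the sign of arrays was flipped.

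Of 30 gene lists, 29 had at least 5 measured genes and were tested; the list of pituitary markers had 4 and was not tested. The test was limma's camera in its pre-ranked form (cameraPR) with a preset correlation between genes of 0.01, adjusted over the 29 lists of a comparison. The pre-ranked form replaced the planned camera because genes may miss an array. Camera with an estimated correlation and fry were run on the 5857 genes measured on all 6 arrays. Camera compares a list with the other genes, and fry compares it with no change. Fry's test of change in either direction was added after the results were seen. The lists covered opioid receptors, peptides and regulators; immediate early genes; G protein and cAMP signalling; MAP kinase and calcium kinase signalling; GABA, glutamate and monoamine transmission; neuropeptides; pain-related receptors and mediators; synaptic vesicles; voltage-gated channels; neuron structure; markers of oligodendrocytes, astrocytes, microglia, endothelium and mural cells, choroid plexus and ependyma, and blood; haem, iron and oxidative stress; hypoxia; inflammation; heat shock proteins; oxidative phosphorylation; glycolysis and TCA cycle; cytosolic ribosomal proteins; proteasome; translation factors; splicing factors; and histones and chromatin.

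Genes are named by a rule. For each comparison it takes up to 8 genes per side by size of effect among those past the adjusted threshold whose arrays all go the same way (for the difference, with no overlap of the strains), filled up by the highest moderated statistic where fewer pass. It adds the 3 members with the smallest p of each list that passed, and Oprm1, Oprd1, Oprk1, Oprl1, Penk, Pdyn, Pomc, Pnoc, Fos, Egr1, Junb, Arc, Hba-a1, Hbb-b1 and Hmox1 where measured. Since 0 genes passed, every side was filled by the second part of the rule. The rule named 57 distinct genes, of which 54 have 1 probe and 18 miss a value on at least 1 array. For a gene with 1 probe, no other probe can check its value. Other genes named from a list are the members with the smallest p, and were chosen after their values were seen.

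The procedure was tested on simulated data with 3 arrays per strain. Values were drawn independently from a normal distribution, with the spread that the model estimated for each feature and no position pattern. In each simulation of change, 67, 67 and 66 features were changed at once by 2-, 3- and 4-fold. In a strain mean, 58.2%, 88.1% and 97.0% of the changed features passed at these folds. In the difference between strains, 10.4%, 67.2% and 90.9% passed. The Benjamini-Hochberg adjustment is stricter when fewer features change, so these rates do not hold for a few changed features. With no change, 0 features passed. For lists, only glycolysis and TCA cycle in NY1DD was simulated: shifted by a log2 of 0.1 it passed in 3 of 20 simulations, by 0.2 in 19 of 20 and by 0.3 in 20 of 20. Genes were drawn independently, while the correlation estimated for this list in the data was 0.182, so these rates do not hold for correlated genes. The power for other lists and comparisons was not tested. The number of arrays limits the precision.

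The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were no centring, arrays scaled to one spread, probes with values on all 6 arrays, no filter, a robust prior, array weights, a replicate block, a strain's own 3 arrays, probes not averaged, estimated correlation, fry, 2-fold and 1.25-fold limits, Spearman correlation, and each array left out in turn. Keeping the values at the lower limit and subtracting the median of each well position of the source plates on each array (well position correction) were added after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.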

Results

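The data are log2 ratios, likely of naloxone over saline (in the reverse case every sign below turns, and higher reads as lower), of 9685 features in mouse brain 10 min after injection: 3 arrays of NY1DD mice, a transgenic sickle cell model, and 3 arrays of wild-type C57BL/6J mice. Usable probes numbered 11155, 11232 and 11357 on NY1DD replicates 1 to 3, and 11413, 11317 and 11333 on C57BL/6J replicates 1 to 3. The medians of the deposited natural log ratios were 0.0127, 0.0378 and 0.0108 on the NY1DD arrays and 0.0247, 0.0104 and 0.0172 on the C57BL/6J arrays. The SD of the log2 ratios was 0.58, 0.59 and 0.48 on the NY1DD arrays and 0.44, 0.48 and 0.55 on the C57BL/6J arrays. The share of probes past 1.5-fold was 23.7%, 21.5% and 12.3% on the NY1DD arrays and 11.2%, 11.8% and 18.3% on the C57BL/6J arrays. Across features, which are not independent replicates, the Pearson correlation between arrays ran from 0.0194 to 0.191 within NY1DD, from 0.124 to 0.148 within C57BL/6J and from -0.0701 to 0.178 between strains. The position of a probe in the wells of the source plates accounted for 27.5% of the variance on NY1DD replicate 2 and for 3.20% to 11.4% on the other 5 arrays.

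**Figure D1:**
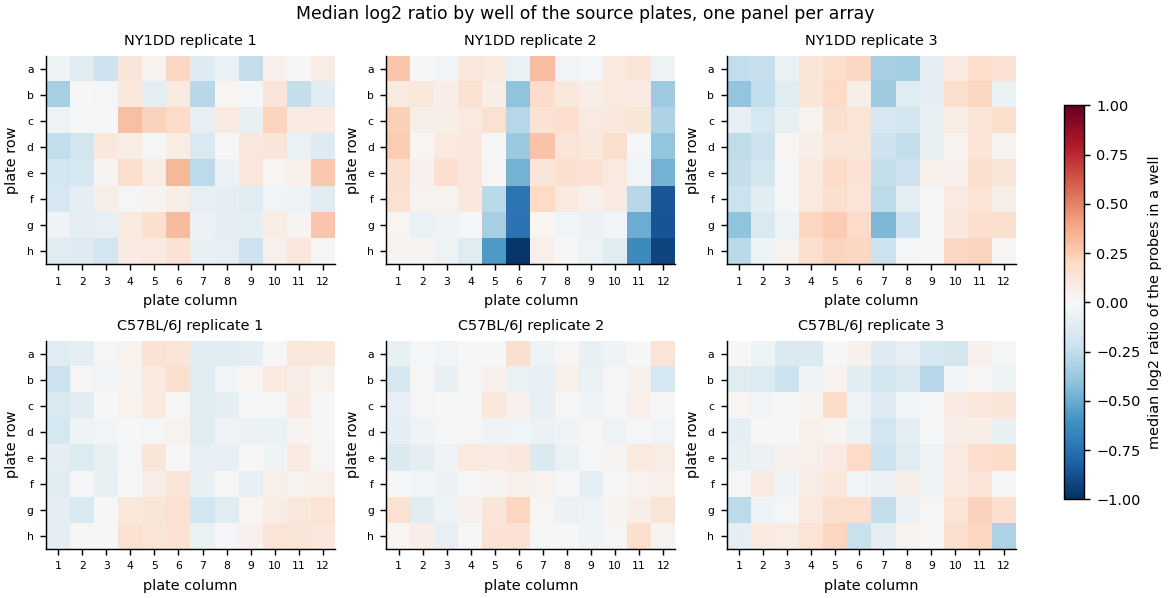
Median log2 ratio of the probes in each of the 96 wells of the source plates (12 columns by 8 rows), 1 panel per array, colour scale from -1 to 1. On NY1DD replicate 2 the well medians run from -0.97 to 0.31, with the low wells in columns 5, 6, 11 and 12, while on the other 5 arrays they stay between -0.45 and 0.33.

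The first comparison asks which brain transcripts respond to naloxone in sickle cell mice. The positive genes named for NY1DD include St3gal4, a sialyltransferase, with a mean log2 ratio of 3.12 (SE 0.43, n = 2 arrays), Mpp6, a membrane scaffold protein, with 1.91 (SE 0.30, n = 2), Rcbtb2 with 1.44 (SE 0.26, n = 3), Taf13, a subunit of a general transcription factor, with 1.38 (SE 0.20, n = 2), and Tsc22d4 with 1.31 (SE 0.22, n = 2). Psmc5, an ATPase of the proteasome, had the narrowest SE of the positive genes, with 0.94 (SE 0.15, n = 3, limma adjusted p = 0.368) and an SD between arrays of 0.07. Pdcd5 and B9d2, a protein of the primary cilium, had 1.00 (SE 0.20) and 0.91 (SE 0.18), each with n = 3. The negative genes were led by Dennd3, an exchange factor for Rab proteins, with -1.55 (SE 0.14, n = 3, limma adjusted p = 0.271, the smallest of this comparison). The other negative genes were Cysltr1, a leukotriene receptor, with -2.15 (SE 0.29, n = 3), Cldn3, a tight junction protein, with -2.04 (SE 0.34, n = 2), Hpca, a neuronal calcium sensor, with -2.01 (SE 0.25, n = 2), Ntng2, a neuronal adhesion protein, with -1.90 (SE 0.30, n = 2), Eri1, an RNA exonuclease, with -1.70 (SE 0.26, n = 3), Ccnk, a cyclin of transcription, with -1.27 (SE 0.20, n = 2), and Ergic2, a protein of the early secretory pathway, with -1.10 (SE 0.17, n = 3). None of these 16 genes passed: their limma adjusted p ran from 0.271 to 0.430. Dennd3, Cysltr1, Eri1 and Ntng2, 4 of the 8 negative genes, lie in plate column 12, which holds 8.32% of all probes and whose well medians ran from -0.92 to -0.05 on NY1DD replicate 2. After the well position correction, chosen after seeing the data, their means were -1.25, -1.97, -1.54 and -1.42. Ccnk, Cldn3, Ergic2 and Hpca lie in columns 1, 7, 7 and 8. Their well medians were -0.12, -0.08, -0.26 and -0.07 on NY1DD replicate 1. On NY1DD replicate 3, where Hpca has no value, they were -0.27, -0.27, -0.24 and -0.34. With the values at the lower limit kept, also a choice made after seeing the data, the NY1DD mean of Ntng2 was -3.49.

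Of the 9685 features, 0 passed in NY1DD (limma), and 809 had an unadjusted p under 0.05 (335 positive, 474 negative) against 484 expected by chance. All arrays of a feature had the same sign for 29.6% of features, against 26.0% by chance. The size rule held for 58 features (21 positive, 37 negative), against 16 to 34 after flipping the sign of arrays.

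Lists near the drug's target did not pass in NY1DD. Among 11 measured genes of opioid receptors, peptides and regulators, 5 were positive and 6 negative (median -0.04, mean 0.07, adjusted p = 0.580). Penk, the precursor of the enkephalins, had the second smallest p of that list, with a mean log2 ratio of 0.35 (SE 0.15, SD 0.19, n = 3, limma adjusted p = 0.588), after Cpe, a prohormone-processing enzyme, with 0.33. Immediate early genes, which respond fast to neuronal activity, were positive for 10 of 15 (median 0.04, adjusted p = 0.432). Among these, Fosl2 had 0.38 (SE 0.14, n = 3) and Ier5 had 0.79 (SE 0.31, n = 3). G protein and cAMP signalling had 20 of 32 genes positive (median 0.05, adjusted p = 0.460). Its anchoring protein Akap12 had -1.24 (SE 0.28, n = 3), and the phosphodiesterases Pde4a and Pde4b both had 0.53 (SE 0.15 and 0.18, n = 3). MAP kinase and calcium kinase signalling had 15 of 29 positive (median 0.02, adjusted p = 0.480). Its kinase Camk2a had 0.62 (SE 0.20, n = 3). The lists of GABA transmission (6 of 15 positive, median -0.06, adjusted p = 0.654), glutamate transmission (11 of 23, median -0.02, adjusted p = 0.762), monoamine transmission (4 of 6, median 0.13, adjusted p = 0.580) and neuropeptides (5 of 10, median 0.11, adjusted p = 0.932) did not pass. Among the neuropeptides, Bdnf had 0.58 (SE 0.21), Cartpt -0.46 (SE 0.16) and Chga -0.35 (SE 0.12), each with n = 3.

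Energy and protein turnover lists came closest to the threshold in NY1DD, with none of the 29 lists past it. Glycolysis and TCA cycle had 22 of 28 genes positive (median 0.17, adjusted p = 0.0606), led by Aldoa, a glycolytic aldolase, with 0.80 (SE 0.18, n = 3). The cytosolic ribosomal proteins had 28 of 41 positive (median 0.12, adjusted p = 0.0784) and the proteasome 18 of 29 (median 0.06, adjusted p = 0.106). With the estimated correlation, the smallest adjusted p of any list in NY1DD was 0.740. Without NY1DD replicate 2, the array with the position pattern, 4 lists passed in NY1DD: cytosolic ribosomal proteins (adjusted p = 0.00430), glycolysis and TCA cycle (0.0102), and the proteasome and MAP kinase and calcium kinase signalling (both 0.0127). With all arrays and the well position correction, cytosolic ribosomal proteins (adjusted p = 0.00512), glycolysis and TCA cycle (0.00575) and proteasome (0.00622) passed; glycolysis and TCA cycle also passed without NY1DD replicate 3 (0.0164).

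Markers of cell types did not pass in NY1DD. Endothelial and mural markers were positive for 15 of 22 genes (median 0.06, adjusted p = 0.176), oligodendrocyte and myelin markers for 17 of 26 (median 0.03, adjusted p = 0.572), and astrocyte markers for 6 of 21 (median -0.11, adjusted p = 0.580). Microglia and macrophage markers were positive for 4 of 8 (median -0.02, adjusted p = 0.699), with Laptm5, a lysosomal protein, at 0.54 (SE 0.14, n = 3). Choroid plexus and ependyma markers had 4 of 12 positive (median -0.08, adjusted p = 0.762), and blood and red cell markers 4 of 8 (median 0.02, adjusted p = 0.797). Lists tied to sickle cell disease did not pass either, and their members went both ways. Haem, iron and oxidative stress had 15 of 26 genes positive (median 0.04, adjusted p = 0.580), among them the ferritin gene Fth1 with 0.41 (SE 0.16, n = 3) and the iron regulator Ireb2 with 0.34 (SE 0.13, n = 3), while Aco1, an aconitase that also regulates iron genes, had -0.64 (SE 0.21, n = 3). Hypoxia response had 7 of 14 positive (median 0.01, adjusted p = 0.762). Inflammation and cytokine signalling had 6 of 11 positive (median 0.02, mean -0.10, adjusted p = 0.699), with the NF-kappaB pathway genes Ikbkb and Nfkbib at -1.28 (SE 0.35, n = 3) and -0.40 (SE 0.15, n = 3). Adjusted over the list alone, 1 gene each passed in microglia and macrophage markers (Laptm5), hypoxia response (Aldoa) and proteasome (Psmc5), and 0 passed over all features. In 8 of the 29 lists the signs of the median, the mean and the test differed in NY1DD, the opioid list among them.

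**Figure D2:**
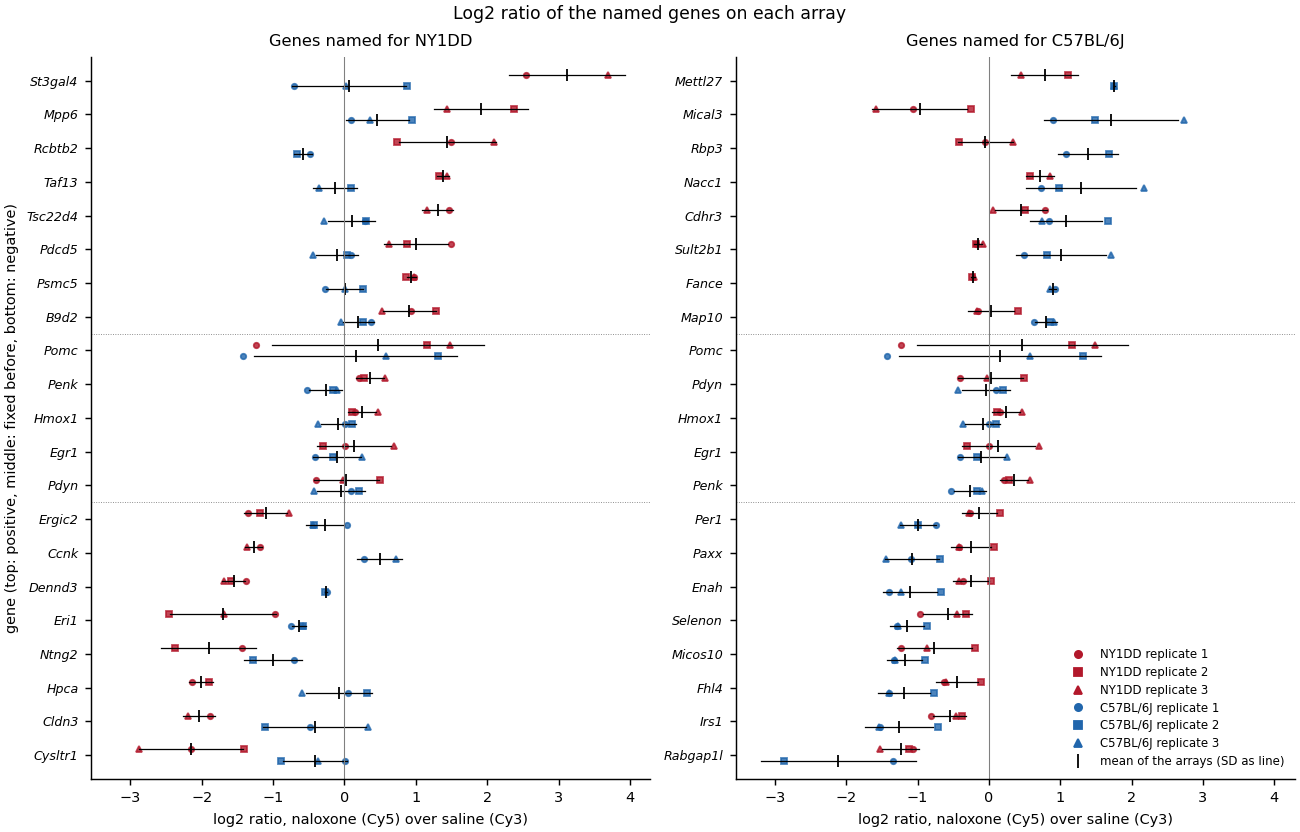
Log2 ratio (horizontal axis) of the genes named for NY1DD (left) and for C57BL/6J (right) on each array, with NY1DD arrays in red and C57BL/6J arrays in blue, the mean as a tick and the SD between arrays as a line. Psmc5 has a mean of 0.94 in NY1DD and 0.00 in C57BL/6J, and Per1 has -0.13 in NY1DD and -0.99 in C57BL/6J; 0 of these genes passed the adjusted test.

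The second comparison asks the same of naloxone in wild-type mice. In C57BL/6J the negative side was led by Selenon, a selenoprotein, with a mean log2 ratio of -1.15 (SE 0.18, n = 3), Fhl4 with -1.19 (SE 0.19, n = 3), Irs1, an adaptor of the insulin receptor, with -1.26 (SE 0.20, n = 3), and Per1, a circadian clock repressor and immediate early gene, with -0.99 (SE 0.16, n = 3). Enah, an actin regulator, had -1.10 (SE 0.18, n = 3), Paxx, a DNA end-joining factor, -1.07 (SE 0.19, n = 3), Micos10, a protein of mitochondrial cristae, -1.18 (SE 0.21, n = 3), and Rabgap1l, a GTPase-activating protein for Rab proteins, -2.11 (SE 0.36, n = 2). The positive side held Mettl27 with 1.76 (SE 0.23, n = 2), Mical3, an actin-oxidising enzyme, with 1.71 (SE 0.37, n = 3), Rbp3, a retinoid-binding protein, with 1.38 (SE 0.25, n = 2), Nacc1, a transcriptional regulator, with 1.29 (SE 0.29, n = 3), Cdhr3, a cadherin-related protein, with 1.08 (SE 0.23, n = 3), Sult2b1, a sterol sulfotransferase, with 1.01 (SE 0.23, n = 3), Fance, a DNA repair protein, with 0.89 (SE 0.18, n = 2), and Map10, a microtubule protein, with 0.80 (SE 0.16, n = 3). None passed: the limma adjusted p of these 16 genes ran from 0.196 to 0.267. With the values at the lower limit kept, a choice added after seeing the data, Mettl27 turned to -1.06 and Rabgap1l went to -3.63. Of the 8 negative genes, 7 belong to a set of 85 features past 1.5-fold below 0 on every C57BL/6J array, of which 67 have no gene symbol here and whose median NY1DD mean was -0.44.

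Of the 9685 features, 0 passed in C57BL/6J (limma), and 671 had an unadjusted p under 0.05 (170 positive, 501 negative) against 484 expected by chance. All arrays had the same sign for 31.7% of features, against 25.5% by chance. The size rule held for 94 features (9 positive, 85 negative), against 12 to 21 after flipping the sign of arrays, and for 145 with arrays scaled to one spread.

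In C57BL/6J, genes of synaptic vesicle and release were positive for 23 of 29 (median 0.12, adjusted p = 0.192), and in NY1DD for 17 of 29 (median 0.03, adjusted p = 0.432); the difference between strains had a median of -0.06 and a mean of 0.01 (adjusted p = 0.902). The release proteins Snap25 and Vamp2 had 0.64 (SE 0.16, n = 3) and 0.37 (SE 0.13, n = 3) in C57BL/6J, and the synaptic vesicle protein Syn1 had 1.06 (SE 0.34, n = 3) in NY1DD. Endothelial and mural markers were positive for 17 of 22 (median 0.06, adjusted p = 0.192), oligodendrocyte and myelin markers for 21 of 26 (median 0.07, adjusted p = 0.462) and astrocyte markers for 13 of 21 (median 0.07, adjusted p = 0.869). Immediate early genes were negative for 10 of 15 (median -0.09, adjusted p = 0.462), with Per1 at -0.99 and Jund at -0.40 (SE 0.15, n = 3), while Srf had 0.45 (SE 0.14, n = 3). Per1 rests on 1 probe and is among the 85 features past 1.5-fold below 0 on every C57BL/6J array. Histones and chromatin were negative for 20 of 28 (median -0.10, adjusted p = 0.462), and inflammation and cytokine signalling for 8 of 11 (median -0.22, adjusted p = 0.808). GABA transmission was negative for 9 of 15 (median -0.01, adjusted p = 0.869), where Gad1, which makes GABA, had -0.95 (SE 0.23, n = 3). The opioid list had 6 of 11 genes positive (median 0.03, adjusted p = 0.996), with Penk at -0.26 (SE 0.15, SD 0.23, n = 3, limma adjusted p = 0.861). All 6 genes of monoamine transmission were negative (median -0.09, adjusted p = 0.672). None of the 29 lists passed in C57BL/6J, and the smallest adjusted p with the estimated correlation was 0.852. Synaptic vesicle and release passed without NY1DD replicate 2 (adjusted p = 0.0318), without NY1DD replicate 3 (0.0456) and without C57BL/6J replicate 2 (0.0483); with all arrays and the estimated correlation its adjusted p was 0.852. Adjusted over the list alone, 1 immediate early gene (Per1) and 1 choroid plexus and ependyma marker (Dynlrb2, a dynein light chain, -0.81, SE 0.19, n = 3) passed, and 0 over all features. In 6 of the 29 lists the signs of the median, the mean and the test differed in C57BL/6J.

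The third comparison asks whether the response differs between sickle cell and wild-type mice; a dye bias common to all arrays cancels here. The cytosolic ribosomal proteins, which build the ribosome, were higher in NY1DD than in C57BL/6J for 31 of 41 genes, by a median of 0.16 and a mean of 0.16 (adjusted p = 0.0429, the only list of 29 past the threshold). This call was lost with the estimated correlation (adjusted p = 0.907) and with fry (adjusted p = 0.860). The median of the list had a mean over arrays of 0.17 (SD 0.19, n = 3) in NY1DD and -0.02 (SD 0.17, n = 3) in C57BL/6J, and its arrays overlapped. Its members Rpl21, Rps18 and Rps19 differed by 0.66 (SE 0.25), 0.89 (SE 0.49) and 0.37 (SE 0.23), and 0 of the 41 passed, over all features or adjusted over the list alone. The call also ended without NY1DD replicate 1 (adjusted p = 0.599), NY1DD replicate 3 (0.0781), C57BL/6J replicate 1 (0.527) or C57BL/6J replicate 3 (0.108), with arrays scaled to one spread (0.0602) and with a replicate block (0.0785). Without NY1DD replicate 2 its adjusted p was 0.000188, and the proteasome passed beside it (adjusted p = 0.0294). With all arrays, the adjusted p of the proteasome was 0.907 with the estimated correlation and 0.860 with fry.

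The immediate early genes were higher in NY1DD for 11 of 15 (median 0.19, adjusted p = 0.0724); they passed with no filter (0.0441) and without NY1DD replicate 1 (0.0333). With all arrays, their adjusted p was 0.907 with the estimated correlation and 0.860 with fry. Per1 and Ier5 differed by 0.86 (SE 0.23) and 1.21 (SE 0.43). Per1 rests on 1 probe and belongs to the 85 features past 1.5-fold below 0 on every C57BL/6J array. Histones and chromatin were higher in NY1DD for 19 of 28 (median 0.14, adjusted p = 0.184) and the proteasome for 18 of 29 (median 0.06, adjusted p = 0.228). All 6 monoamine transmission genes were higher in NY1DD (median 0.14, adjusted p = 0.406), as were 44 of 66 oxidative phosphorylation genes (median 0.07, adjusted p = 0.406). Astrocyte markers were lower in NY1DD for 15 of 21 (median -0.08, adjusted p = 0.630). The opioid list was higher for 6 of 11 (median 0.07, adjusted p = 0.838). In 8 of the 29 lists the signs of the median, the mean and the test differed between strains.

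Single genes with the strains' arrays apart included St3gal4 with a difference of 3.05 (SE 0.55), Rcbtb2 with 2.02 (SE 0.41), Herc4, a ubiquitin ligase, with 1.68 (SE 0.38), Taf13 with 1.51 (SE 0.28), 1700030K09Rik with 1.22 (SE 0.27), Ntn3, a netrin, with 1.03 (SE 0.22), Rgs7, a neuronal regulator of G protein signalling, with 0.98 (SE 0.22), and Psmc5 with 0.94 (SE 0.21). Both probes of Rgs7 went the same way, with NY1DD means of 0.31 and 0.55 and C57BL/6J means of -0.66 and -0.36. Lower in NY1DD were Mical3 with -2.68 (SE 0.53), Igdcc3 with -2.16 (SE 0.48), Hpca with -1.93 (SE 0.32), Nectin3, an adhesion protein, with -1.80 (SE 0.38), Ccnk with -1.77 (SE 0.29), Rbp3 with -1.43 (SE 0.32), Dennd3 with -1.29 (SE 0.22) and Fance with -1.12 (SE 0.25). None of these 16 genes passed (limma adjusted p = 0.969 for each), and St3gal4, Taf13, Rcbtb2, Hpca, Ccnk, Nectin3, Rbp3, Dennd3 and Fance had values on 2 arrays in at least 1 strain, the others on 3 in each. With the values at the lower limit kept, Ccnk turned to 0.62 and Dennd3 to 0.85. Of the 9685 features, 0 differed (limma), and 436 had an unadjusted p under 0.05 (266 positive, 170 negative) against 484 expected by chance; without C57BL/6J replicate 3 it was 282. The strains' arrays did not overlap for 10.2% of features, against 10.6% by chance. Across features, the mean log2 ratios of the strains had a Pearson correlation of 0.232. A dye bias common to all arrays does not cancel in this correlation, so it does not show a shared response to naloxone.

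The fourth comparison asks for a response common to both strains, where a common dye bias stays in the average. Endothelial and mural markers were positive for 17 of 22 genes (median 0.09, mean 0.11, adjusted p = 0.0476). Of these, Ly6e, a membrane protein of brain endothelium, averaged 0.39 (SE 0.09), with 0.37 (SD 0.03, n = 3) in NY1DD and 0.41 (SD 0.08, n = 3) in C57BL/6J. Myl9, a smooth muscle myosin chain, averaged 0.39 (SE 0.14), and Slco1a4, an anion transporter of the blood-brain barrier, 0.26 (SE 0.10). Their means were 0.53 and 0.47 in NY1DD, and 0.25 and 0.06 in C57BL/6J, where each had an array below 0. The call of endothelial and mural markers was lost with the estimated correlation (adjusted p = 0.704). Fry, run on 20 of the 22 genes, gave an adjusted p of 0.0247. It compares the list with no change and not with other genes, so it answers another question, and a common dye bias stays in it. Glycolysis and TCA cycle were positive for 23 of 28 genes (median 0.08, mean 0.10, adjusted p = 0.0476), with Pkm, a pyruvate kinase, at 0.37 (SE 0.12), Aldoa at 0.33 (SE 0.13) and Tpi1, a triose phosphate isomerase, at 0.25 (SE 0.10). Here the adjusted p was 0.887 with the estimated correlation and 0.556 with fry. In the single strains, the adjusted p of this list was 0.0606 in NY1DD and 0.658 in C57BL/6J. Aldoa had 0.80 (SD 0.41, n = 3) in NY1DD and -0.14 (SD 0.19, n = 3) in C57BL/6J, so its average does not show a response common to both strains. In both lists 0 genes passed, over all features or adjusted over the list alone.

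Both calls sat close to the threshold. With arrays scaled to one spread both had an adjusted p of 0.0561, with no filter 0.0534, and with the lower limit kept 0.0595. With array weights the adjusted p of endothelial and mural markers was 0.0834 and that of glycolysis and TCA cycle 0.0646. Endothelial and mural markers kept their call without C57BL/6J replicate 2 (0.0448) and lost it without NY1DD replicates 1, 2 and 3 (0.0563, 0.110 and 0.0910) and C57BL/6J replicates 1 and 3 (0.0624 and 0.0953). Glycolysis and TCA cycle kept theirs without NY1DD replicates 2 and 3 (0.0247 and 0.0145) and lost it without NY1DD replicate 1 (0.824) and C57BL/6J replicates 1, 2 and 3 (0.184, 0.105 and 0.0676). The list of synaptic vesicle and release, positive for 20 of 29 (median 0.11, adjusted p = 0.120), passed without NY1DD replicate 2 (0.0215), without C57BL/6J replicate 2 (0.0448) and with probes measured on all 6 arrays (0.0429). MAP kinase and calcium kinase signalling passed without NY1DD replicate 2 (0.0474). With all arrays and the estimated correlation, the adjusted p of these lists was 0.887 and 0.983.

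**Figure D3:**
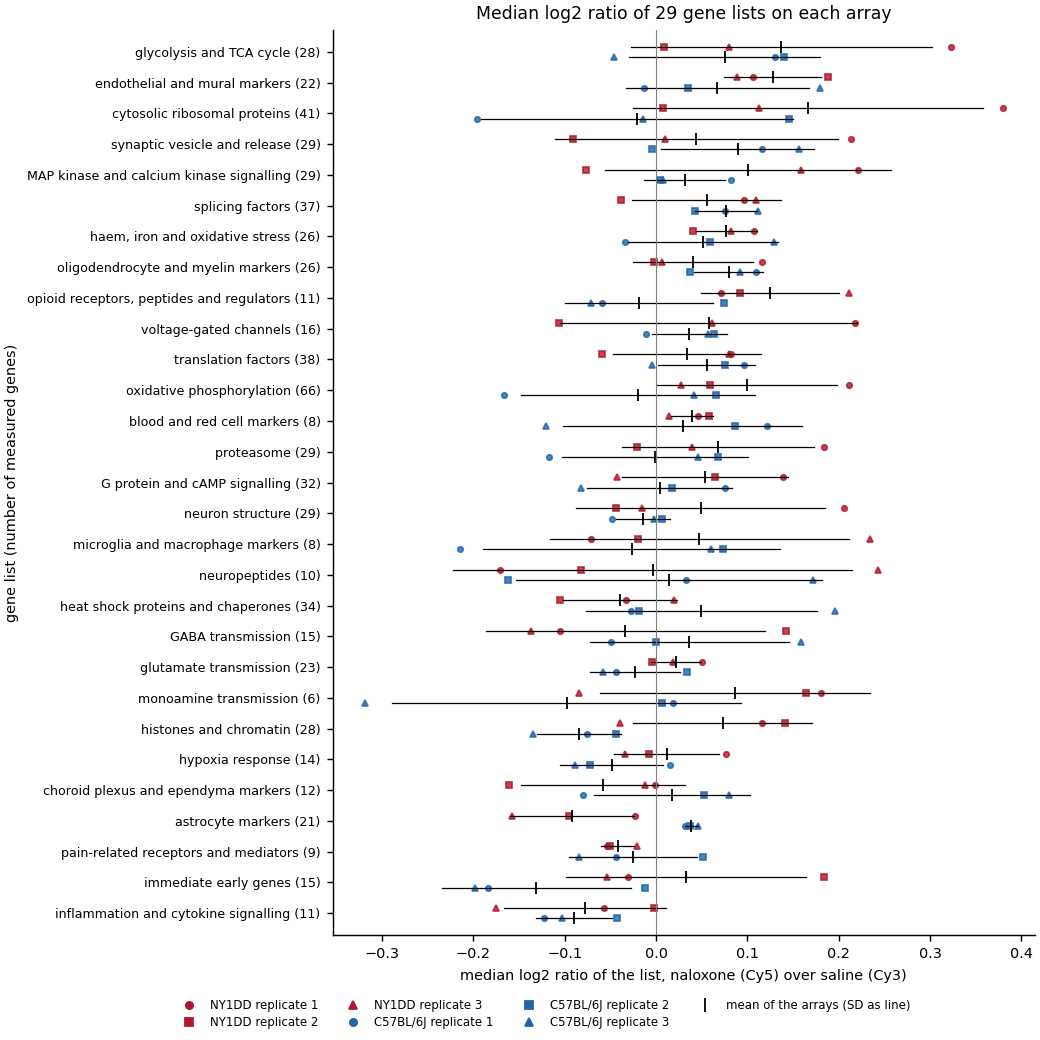
Median log2 ratio (horizontal axis) of 29 gene lists on each array, with NY1DD in red and C57BL/6J in blue, the mean of the 3 array medians as a tick and their SD as a line. The cytosolic ribosomal proteins lie at 0.38, 0.01 and 0.11 on the NY1DD arrays and at -0.20, 0.15 and -0.01 on the C57BL/6J arrays.

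Averaged over strains, the positive genes named were Mettl27 with 1.27 (SE 0.16), Slc14a1, a urea transporter, with 1.24 (SE 0.28), Mpp6 with 1.19 (SE 0.20), Ahr, a ligand-activated transcription factor, with 0.78 (SE 0.17), Cdhr3 with 0.77 (SE 0.16), Slc35c1, a transporter of activated fucose, with 0.76 (SE 0.15), Lpin2, a phosphatidate phosphatase, with 0.74 (SE 0.15), and Atp2b4, a calcium pump of the plasma membrane, with 0.54 (SE 0.12). The negative genes were Rabgap1l with -1.67 (SE 0.23), Ntng2 with -1.45 (SE 0.21), Eri1 with -1.17 (SE 0.18), Micos10 with -0.97 (SE 0.15), Dennd3 with -0.91 (SE 0.11), Irs1 with -0.90 (SE 0.14), Selenon with -0.86 (SE 0.12) and Fhl4 with -0.82 (SE 0.13). None of these 16 genes passed (limma adjusted p from 0.171 to 0.232), and Mettl27, Slc14a1, Mpp6, Ahr, Rabgap1l, Ntng2 and Dennd3 had values on 2 arrays in at least 1 strain, the others on 3 in each. Of the negative genes, 4 belong to the 85 features described for C57BL/6J. With the values at the lower limit kept, Mettl27 turned to -0.14 and Slc14a1 to -0.06, while Dennd3 went to -1.97 and Ntng2 to -3.19. Of the 9685 features, 0 passed (limma), and 1043 had an unadjusted p under 0.05 (329 positive, 714 negative) against 484 expected by chance. All arrays had the same sign for 7.37% of features, against 3.33% by chance. Adjusted over the list alone, 3 choroid plexus and ependyma markers passed (Slc4a5 with -0.54, Folr1 with 0.60 and Dynlrb2 with -0.44), with 1 immediate early gene (Per1 with -0.56) and 1 microglia and macrophage marker (Laptm5 with 0.40). Per1 also belongs to the 85 features. The signs of the median, the mean and the test differed in 9 of the 29 lists.

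Of the genes of the opioid system fixed in advance, Penk differed between strains by 0.62 (SE 0.21, n = 3 per strain, limma adjusted p = 0.969). The arrays of the strains did not overlap for Penk, and its 2 probes went the same way: 0.46 and 0.25 in NY1DD, -0.14 and -0.39 in C57BL/6J. Pomc, the precursor of beta-endorphin, varied most of these genes, with 0.47 (SD 1.48, n = 3) in NY1DD and 0.16 (SD 1.42, n = 3) in C57BL/6J. Pdyn, the precursor of the dynorphins, had 0.03 (SD 0.45, n = 3) and -0.04 (SD 0.34, n = 3). The activity-induced gene Egr1 had 0.13 (SD 0.52, n = 3) in NY1DD and -0.11 (SD 0.33, n = 3) in C57BL/6J, and Hmox1, the haem-degrading oxygenase, 0.24 (SD 0.20, n = 3) and -0.09 (SD 0.25, n = 3). The receptor genes Oprm1, Oprd1, Oprk1 and Oprl1, and Pnoc, Fos, Junb, Arc, Hba-a1 and Hbb-b1, had no usable probe and were not analysed here.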

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

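In this part, the tests of the position pattern, of the 85 negative C57BL/6J features, and of position and strain for the ribosomal list were chosen only after those results were seen.

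The difference between strains in the cytosolic ribosomal proteins stood out because it was tested as a difference itself and passed (adjusted p = 0.0429; higher in NY1DD for 31 of 41 genes, median 0.16). The call was lost with an estimated correlation (adjusted p = 0.907) and with fry (adjusted p = 0.860). Well position is argued against as the whole cause: after each well's median was subtracted, the mean difference went from 0.16 to 0.21. The SE over genes was 0.04 for both and treats the genes as independent. The adjusted p was 0.00202 with the preset correlation of 0.01, while the correlation estimated for this list was 0.236. The corrected values were not tested with the estimated correlation, so this p does not restore the call. A dye trend with signal may remain: the list lay at percentile 99.8 of 10000 random lists matched on probes per gene, but genes with 3 or more probes differed from genes with 1 probe by only -0.01 (SE 0.01), so this stand-in for abundance had nothing to match and the test decides nothing. Strain stays open too, since the 6 array medians overlapped (exact two-sided permutation p = 0.4, where 3 against 3 arrays can give no p below 0.1). The 10 ways to split the 6 arrays into 3 and 3 cannot give a share under 0.05; the real split called 1 list, and the highest of the others called 2.

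The position pattern on NY1DD replicate 2 covers 27.5% of that array's variance, against 3.20% to 11.4% on the other arrays and at most 1.38% in 200 random assignments of wells on any array. Wells 6 columns apart had nearly the same median there (correlation 0.983 over 48 pairs of wells), and this correlation was 0.809 to 0.946 on the other 5 arrays. The repeat is thus common to all 6 arrays. It fits neighbouring spots sharing a position if both sets of wells were printed side by side. The print layout is not given in the sources used here. A response of NY1DD mice does not account for the pattern on NY1DD replicate 2. The well medians of that array ran against those of the other NY1DD arrays (correlation -0.348 and -0.452) and of the C57BL/6J arrays (-0.543, -0.490 and -0.208), while the other 5 arrays correlated at 0.44 to 0.85 among themselves.

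The 85 features past 1.5-fold below 0 on every C57BL/6J array include 67 with no gene symbol here (78.8%, against 36.5% of all features, Fisher exact p = 2.18e-15). This p treats the features as independent, although they were chosen on the same arrays and many share plate columns. A response in C57BL/6J alone is argued against as the whole cause by the median of these features in the NY1DD means, -0.44, with 84 of 85 below 0. After well position correction it was -0.38, with 82 of 85 below 0. The lowest of 10000 random sets had -0.15, but these sets were not matched on plate column or on having a symbol. A response in C57BL/6J added to a bias shared by both strains would give the same and cannot be told apart. The NY1DD arrays were uneven, with medians of -0.81, -0.09 and -0.47 on replicates 1 to 3, and -0.70, -0.17 and -0.32 after well position correction. The mirror set of 37 features past 1.5-fold below 0 on every NY1DD array, had a median of -0.28 in the C57BL/6J means, with 28 of 37 below 0. Well position is argued against as the whole cause by its size: the lowest well medians on C57BL/6J replicates 1 to 3 were -0.22, -0.18 and -0.31. The medians of these features there went from -1.13, -0.77 and -1.46 to -1.09, -0.72 and -1.38 after the correction. With well medians this small they had to stay past 1.5-fold, so that outcome is no further test. The least negative had an exact 95% interval of -0.77 to -0.68, over features chosen on these same arrays and not independent. As part of the cause, well position cannot be told apart: 59 of the 86 probes of these features (68.6%) sit in plate columns 1, 2, 7 and 8, against 32.9% of all probes. After the correction, 64 features (75.3%, exact 95% interval 64.7% to 84.0%) stayed past 1.5-fold on all 3 arrays. Position on a finer scale than the well was not tested. A dye bias of single probes common to all arrays may be at work, given that 98.8% of the features were below 0 in the NY1DD mean. On NY1DD replicate 2 alone, 57 of 83 were below 0, with a median of -0.09. A response shared by both strains would also give a negative NY1DD mean, and no dye swap exists to part them.

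For the difference between strains, 0 features passed in the real split and 0 in the highest of the other 9 splits. At an unadjusted p under 0.05 the real split gave 436 features, the highest of the others gave 537, and 3 of the 10 splits gave at least as many as the real one. As 10 splits cannot give a share under 0.05, these counts say no more than that.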

How the results depend on the processing

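Keeping the lower limit and the well position correction were chosen after seeing the data; all other alternatives were planned. Under the 66 alternative values of the 4 counts of features past the adjusted threshold, the count was 0 each time. Of 168 alternative values of the counts and of the correlation between strains, 126 were the same by the rule of 1.5 times for counts. Of 1278 alternative values of named genes, 35 had the opposite sign (20 with an array left out), and 0 named genes passed.

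The number of lists that passed changed with the setting. Between strains 1 list passed, against 0 with arrays scaled to one spread, with the replicate block, with the estimated correlation and with fry, and 2 with no filter. Averaged over strains 2 passed, against 0 with arrays scaled, no filter, array weights, the lower limit kept or the estimated correlation, and 1 with fry. In NY1DD 0 passed, against 2 with array weights, 1 with the lower limit kept and 3 with the well position correction. With an array left out, the lists passing ranged from 0 to 4 in NY1DD, 0 to 1 in C57BL/6J, 0 to 2 between strains and 0 to 3 averaged. Over all its alternatives, the adjusted p of the ribosomal list ran from 0.000188 to 0.907, of endothelial and mural markers from 0.0247 to 0.704 and of glycolysis and TCA cycle from 0.0145 to 0.887. The cause was not tested.

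The size rule gave 58 features in NY1DD and 94 in C57BL/6J; it gave 9 and 4 at 2-fold and 277 and 359 at the lower of the alternative limits, which have to lower and raise the counts, and 145 in C57BL/6J with arrays scaled. With an array left out it gave 203 to 304 in NY1DD and 202 to 299 in C57BL/6J, where fewer arrays have to pass. The correlation of the strains' mean log2 ratios, 0.232, in which a common dye bias stays, ranged from 0.148 to 0.288 with an array left out. Features at an unadjusted p under 0.05 numbered 523 in NY1DD with its own 3 arrays, against 809, and 282 between strains without C57BL/6J replicate 3, against 436.

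Some signs turned. Pdyn averaged 0.020 with no centring and 0.021 with arrays scaled, and Egr1 averaged -0.0055 with arrays scaled. With array weights Pdyn was -0.015 in NY1DD, 0.020 in C57BL/6J, -0.035 between strains and 0.0026 averaged, and Pomc was -0.028 in C57BL/6J. With the well position correction Pdyn was -0.049 in NY1DD and -0.018 between strains. With an array left out, Pdyn ranged from -0.21 to 0.24 in NY1DD, -0.17 to 0.15 in C57BL/6J, -0.17 to 0.28 between strains and -0.13 to 0.098 averaged. Egr1 ranged from -0.15 to 0.35, -0.28 to 0.046, -0.045 to 0.46 and -0.13 to 0.12 in the same order. Pomc ranged from -0.035 to 1.32 in NY1DD, -0.42 to 0.95 in C57BL/6J and -0.48 to 1.17 between strains, Penk from -0.0095 to 0.11 averaged, and Hmox1 from -0.18 to 0.053 in C57BL/6J. Without sign change, leaving out an array moved Rps18 to 0.54 to 1.37 and Rps19 to 0.20 to 0.50 between strains, Penk to -0.35 to -0.13, Nacc1 to 0.85 to 1.58 and Sult2b1 to 0.65 to 1.26 in C57BL/6J, Hmox1 to 0.13 to 0.31 in NY1DD, 0.19 to 0.42 between strains and 0.024 to 0.15 averaged, and Aldoa to 0.21 to 0.40 and Pomc to 0.023 to 0.74 averaged. With the lower limit kept, Mettl27 was -1.06 in C57BL/6J and -0.14 averaged, Slc14a1 -0.061 averaged, Ccnk 0.62 and Dennd3 0.85 between strains, since 1 value at the limit then enters each C57BL/6J mean. Dennd3 averaged -1.97 and Rabgap1l was -3.63 in C57BL/6J for the same reason; Ntng2 was -3.49 in NY1DD and averaged -3.19. For the other genes the cause was not tested.

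The replicate block is not a pairing of the arrays: deviations of arrays with the same number correlated at -0.0666, 0.0508 and 0.0197 across features. Probes not averaged gave no value for lists or named genes, and the alternatives planned for linear ratios and for intensities were not run because the values are log ratios. A fit without 1 array assumes that the 2 left in that strain vary like the rest. Signal over background is unknown, so what it limits was not analysed here.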

Other observations

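The tests of agreement between probes were chosen before their values were seen; the other values in this part were chosen for description after the results were seen.

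Lists of neurons and of protein handling not yet described did not pass in either strain. Neuron structure was positive for 18 of 29 genes in NY1DD (median 0.04, adjusted p = 0.432) and 15 of 29 in C57BL/6J (median 0.01, adjusted p = 0.869). The neuronal surface protein Thy1 had log2 ratios of 0.63 (SE 0.21, n = 3) and 0.49 (SE 0.21, n = 3), and the tubulin regulator Stmn1 had 0.25 (SE 0.14, n = 3) in both. Voltage-gated channels were positive for 8 of 16 in both strains (adjusted p = 0.932 and 0.942), and the potassium channel gene Kcnd2 averaged -0.42 (SE 0.17). Pain-related receptors and mediators were positive for 3 of 9 in NY1DD (median -0.14, adjusted p = 0.699) and 5 of 9 in C57BL/6J (median 0.00, adjusted p = 0.996). Of these, Bdnf averaged 0.43 (SE 0.15) over strains and Cckbr, a cholecystokinin receptor, -0.25 (SE 0.11).

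Heat shock proteins and chaperones were positive for 18 of 34 in NY1DD (median 0.01, adjusted p = 0.762) and 21 of 34 in C57BL/6J (median 0.04, adjusted p = 0.816), with the stress-induced Ddit3 at -0.77 (SE 0.18, n = 3) in C57BL/6J. Translation factors were positive for 21 of 38 in NY1DD (median 0.02, adjusted p = 0.572) and 26 of 38 in C57BL/6J (median 0.07, adjusted p = 0.672). Among them Eif2b2 had -0.39 (SE 0.22, n = 3) and -0.89 (SE 0.22, n = 3), and Eef1d had 0.65 (SE 0.15, n = 3) in NY1DD. Splicing factors were positive for 20 of 37 (median 0.00, adjusted p = 0.699) and 26 of 37 (median 0.09, adjusted p = 0.596), with Srsf9 at -0.62 (SE 0.17, n = 3) in C57BL/6J. Oxidative phosphorylation was positive for 42 of 66 genes in NY1DD (median 0.10, adjusted p = 0.319) and 30 of 66 in C57BL/6J (median -0.03, adjusted p = 0.996). Histones and chromatin in NY1DD were positive for 18 of 28 (median 0.07, adjusted p = 0.572). No gene named in these lists passed over all features or adjusted over the list alone.

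Fry's test of change in either direction, which compares a list with no change and not with other genes, gave a p of 6.23e-06 (adjusted p = 0.000181) for haem, iron and oxidative stress in NY1DD, where Aco1, Fth1 and Ireb2 have the smallest p. Of 1000 random lists of as many genes, 0.1% had a p as low. In C57BL/6J the immediate early genes had a p of 0.000196 (adjusted p = 0.00569), with 0.7% of random lists as low, and Per1, Srf and Jund have the smallest p. Averaged over strains 7 lists passed this test, and at least 8% of random lists were as low for each; between strains 0 passed. On simulated data without change, with genes drawn independently, it called 12 lists in 20 simulations for NY1DD and 7 for C57BL/6J. The smallest unadjusted p of this test there was 1.22e-05 and 2.58e-05. The p of the haem list lay below the smallest simulated p of its comparison, and that of the immediate early genes above it. Of the 26 haem genes, 2 positive and 1 negative had an unadjusted p under 0.05 in NY1DD (limma). Of all features, 8.35% had one. A pass in fry's test alone is weak evidence, since lists without change passed too. Per1 belongs to the 85 negative C57BL/6J features, for which a dye bias and well position as part of the cause were not excluded.

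If the ratios carried transcript-specific changes in many genes, different probes of 1 gene would move together. Over 1311 genes with several probes, the correlation of the values of a pair of probes was 0.0194 for NY1DD means, 0.00400 for C57BL/6J means and 0.0220 for the difference between strains. The highest of 1000 random pairings of the same probes gave 0.0694, 0.0795 and 0.0899. A signal shared by the probes of a gene was therefore not detectable over these genes as a set; that few transcripts changed may explain it, as may spots or annotations that do not report the same transcript. The probes of Penk and of Rgs7 went the same way. Rgs7 was named from the average of its probes, and the share of genes whose probes agree in sign was not counted. The agreement in these genes therefore adds no support.

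The control spots left out of the analysis (26 to 29 with a value per array) had an SD of the log2 ratio of 0.42, 0.46 and 0.49 on the NY1DD arrays and 0.36, 0.66 and 0.42 on the C57BL/6J arrays.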
